A study of Mus musculus with 6 samples.

How the data were processed

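Tregs sorted from the spleens of 3 KO and 3 WT male mice aged 45 weeks were profiled on Affymetrix Mouse Gene 2.0 ST arrays, with 1 array per mouse and no technical replicates. Per the labels, each array's deposited values are intensities, summarised per exon-level probe set with PLIER in Affymetrix Expression Console 1.4. The background correction, the normalization between arrays and the annotation version were not given in the sources used here. The deposited intensities were on a linear scale with no offset. Groups and replicate numbers came from the sample titles. The labels name a separate mouse for each sample.

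Intensities were transformed as log2(intensity + 16), so differences of dim probe sets are understated. No further normalization was applied. Gene names came from the platform annotation, which gives symbols only. Of 269751 probe sets 233753 had 1 symbol, 5106 had several and were not used for genes, and 30892 had none. Symbols were kept as the annotation gives them and matched to current names by symbol or unique synonym in a RefSeq table of the GRCm38.p6 assembly, which held 23122 of 23152 names. No coordinates of that table are printed, since no genome build was named for the array values; it served only for names and for membership of a window around Park7. A gene's value was the median of its probe sets with 1 symbol. Genes whose mean log2 value lay under the 40th percentile (5.90) were left out, which removed 9261 genes and left 13891.

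KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. All adjusted p-values of genes come from limma. An exact permutation test of 3 against 3 arrays cannot go below 0.10. Gene lists were tested with limma's camera with a preset correlation of 0.01, with camera with an estimated correlation and with fry, whose p tests movement in one direction and whose mixed p tests change in either direction; neither compares a list with other genes. Lists needed 3 tested members. Of 28 lists 27 were tested, and the list of mitochondrially encoded genes had fewer than 3 tested members. Exon usage was tested with limma's diffSplice (Simes p per gene) over genes with at least 4 probe sets. Genes within 10 Mb of Park7, without Park7 itself, were compared with all others by Fisher's exact test.

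The gene lists, the main tests, the naming rule and the alternatives not said to be added later were fixed before the data were examined; the tests of explanations in the closing section were written later. The rule named Park7; up to 12 genes per direction past the threshold with the largest differences and no overlap of the groups; where fewer than 6 passed, the 10 of that direction with the smallest p, no overlap and a fold of at least 1.3; from each list the members past the threshold over the list alone, or else the 3 with the smallest p; Foxp3, Il2ra, Ctla4, Ikzf2, Mki67, Pdha1 and Pdhb; and the 5 leading genes for exon usage. Predicted and non-coding gene names and antigen receptor segments were left out of the selection by size.

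The tests were checked on simulated arrays with the real probe-set means, with seeded random noise of either the measured or the moderated spread. Over 13891 genes, 53% and 74% of 100 genes changed by 1 log2 unit were recovered under the 2 kinds of spread, and 96% and 100% of 100 genes changed by 2 units. Unchanged genes made up 5.66% and 7.85% of calls. The noise was drawn independently for each gene and probe set, so these shares may not hold for arrays whose genes vary together. The exon usage test failed this check, as its error shares beside the result show, because it gives all probe sets of a gene 1 variance. It was kept as the planned test, and a test with 1 variance per probe set was added after the failure was seen.

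Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of probe sets, bright probe sets only, quantile normalization, median centring, other variance models, an unmoderated test, an adjusted p of 0.10, single probe sets, the replicate number as a block, windows of 5 and 20 Mb and leaving out each array in turn. Exon usage was also run with at least 8 probe sets. Alternatives without the genes within 10 Mb of Park7 were added after the data were seen.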

Results

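Gene expression was measured in regulatory T cells (Tregs), the CD4-positive T cells with high CD25 that restrain immune responses. The cells were sorted from the spleens of 6 male mice aged 45 weeks. 3 mice lacked DJ-1, the protein encoded by Park7 (KO), and 3 were wild-type littermates (WT), so each group held 3 animals with 1 array each. Each array gave intensities for 269751 probe sets, and 13891 genes with a single name entered the tests. The median intensity per array ranged from 88.6 in KO replicate 1 to 100.2 in WT replicate 2. KO replicate 1 had the lowest mean correlation with the other arrays over probe sets, 0.951, against 0.957 to 0.964 for the others. It also lay alone on the first principal component, which held 45.6% of the variance. The number of arrays limits the precision of every value given here.

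The first comparison checked the targeted gene. Park7 was at 9.48 ± 0.21 log2 units in WT and 5.91 ± 0.18 in KO (SD, n = 3 each). The difference was -3.57 (SE 0.16), with a limma adjusted p of 2.06e-05 (0.0905 in an unmoderated test, which passed 0 genes). No fold is given, since the KO mean lay at the filter floor of 5.90. Each KO array lay below each WT array: 9.48, 9.27 and 9.70 in WT replicates 1 to 3, and 6.06, 5.96 and 5.71 in KO replicates 1 to 3. Of the 14 Park7 probe sets, 2 passed when all 269751 probe sets were tested one by one, both lower in KO (-6.19 and -5.66 on the log2(intensity + 16) scale, adjusted p = 0.0117 and 0.0161). These 2 differences are understated, as the offset of 16 is of the order of the lowest KO intensities (9.11 and 36.3). Other probe sets fell without passing, among them 17433313 (-4.92), 17433320 (-4.46), 17433325 (-2.41) and 17433324 (-2.40). Their adjusted p-values were 0.348, 0.350, 0.402 and 0.501, so not passing does not show an unchanged probe set. Probe set 17433317, dim in WT (4.25), differed by 0.47. Probe sets 17433326 and 17433327 differed by 0.20 and -0.36 (adjusted p = 0.839 and 0.820), so the signal lost in KO did not extend to every Park7 probe set. Which part of the gene the knockout removes was not given in the sources used here.

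**Figure D1:**
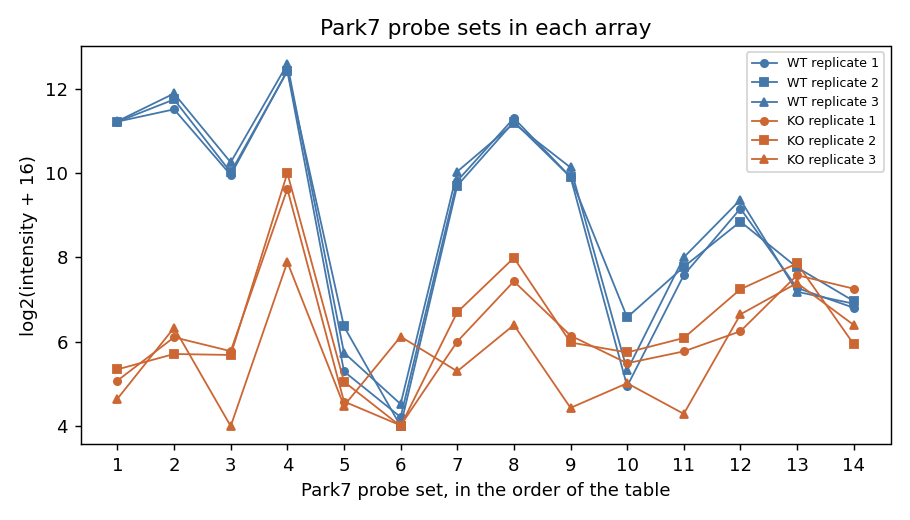
Log2(intensity + 16) of the 14 Park7 probe sets, in the order of the value table, with 1 line per array (blue for the 3 WT arrays, orange for the 3 KO arrays). The first probe set lay at 11.22 on average in WT and 5.03 in KO, whereas the last 2 probe sets overlapped between the groups.

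The second comparison asked which genes differed between KO and WT Tregs. Most genes that passed were lower in KO. Tnfrsf9, the costimulatory receptor 4-1BB, fell from 11.35 ± 0.13 to 8.96 ± 0.79 (-2.40, SE 0.32, adjusted p = 0.0209, n = 3 each). Lag3, an inhibitory receptor that binds MHC class II, fell from 9.24 ± 0.22 to 7.66 ± 0.39 (-1.58, SE 0.21, adjusted p = 0.0198). Il1r2, the decoy receptor for interleukin 1, fell from 10.84 ± 0.55 to 8.74 ± 0.26 (-2.09, SE 0.26, adjusted p = 0.0176). Gzmk, a granzyme of cytotoxic lymphocytes, fell from 8.08 ± 0.20 to 5.99 ± 0.29 (-2.09, SE 0.18, adjusted p = 0.00208).

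In all, 38 of 13891 genes passed an adjusted p of 0.05 in limma, 37 lower and 1 higher in KO, Park7 included. In each of the 38, the 3 KO values lay on one side of the 3 WT values. Over all tested genes 17.4% showed no overlap, where chance gives 10%. Rab6b, a small GTPase of Golgi transport, fell by the most after Park7 (-2.82, SE 0.21, adjusted p = 0.000562). Gp49a (-2.34) and Lilrb4 (-1.60), immunoglobulin-like receptors now named Lilr4b and Lilrb4a, also fell. Their sequences are near-identical, so the signal of each is uncertain. The other genes named by the fixed rule that fell were Atp6v0d2, a subunit of the vacuolar proton pump (-1.80), the endopeptidase Ecel1 (-1.72), the secreted phosphoprotein Spp1, osteopontin (-1.70), the cation exchanger Slc24a3 (-1.70) and the interleukin 13 receptor chain Il13ra1 (-1.43, adjusted p = 0.00869). Tnfrsf1b, a receptor for tumour necrosis factor, fell as well (-1.05, adjusted p = 0.0224), as did the transcription factors Nfil3 (-1.19) and Ahr (-0.97), both named here after their values were seen.

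Clcn6, a chloride-proton exchanger of late endosomes, was the 1 gene that rose, from 7.81 ± 0.09 to 8.78 ± 0.21 (0.97, SE 0.15, adjusted p = 0.0370). It passed in 1 of the 6 fits with an array left out (highest adjusted p 0.241). The fixed rule also named the 10 genes with the smallest p among those that were higher in KO with no overlap and did not pass. They were Kif1b (0.81, adjusted p = 0.0519), Masp2 (1.08, 0.0528), Aak1 (0.78, 0.0554), Eya2 (0.85, 0.0554), the glucocorticoid-induced Tsc22d3 (1.02, 0.0878), Nrg4 (0.66, 0.108), Sp6 (0.76, 0.110), Rps19-ps3 (0.99, 0.112), Zfp933 (0.90, 0.114) and Phxr4 (0.80, 0.128), with the log2 difference and the adjusted p given in that order. Like Clcn6, Kif1b, Masp2, Rps19-ps3 and Zfp933 lay within 10 Mb of Park7.

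The Treg genes named whatever their value did not pass. Foxp3, the lineage transcription factor, was at 12.66 ± 0.02 in WT and 12.73 ± 0.03 in KO (0.06, adjusted p = 0.886). The interleukin 2 receptor chain Il2ra differed by -0.00 (adjusted p = 0.998), the inhibitory receptor Ctla4 by -0.00 (0.992) and the transcription factor Ikzf2 by -0.20 (0.652, and -0.12 without KO replicate 1). Il2ra and Ctla4 were higher in KO by at most 0.034 with quantile normalization or median centring. The sort selected cells with high CD25, the protein that Il2ra encodes, so the similar Il2ra values bear little on an effect of genotype. The series title names pyruvate dehydrogenase, and its subunits Pdha1 (0.13, adjusted p = 0.799) and Pdhb (-0.26, adjusted p = 0.716) did not pass. Arrays give transcript levels only and do not measure the activity of the enzyme. Pdhb differed by -0.0035 without KO replicate 1, -0.14 without WT replicate 3 and -0.44 without KO replicate 2, and Pdha1 by 0.032 without WT replicate 1, 0.076 without KO replicate 2, 0.084 without KO replicate 3, 0.21 without WT replicate 3 and 0.22 without KO replicate 1.

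**Figure D2:**
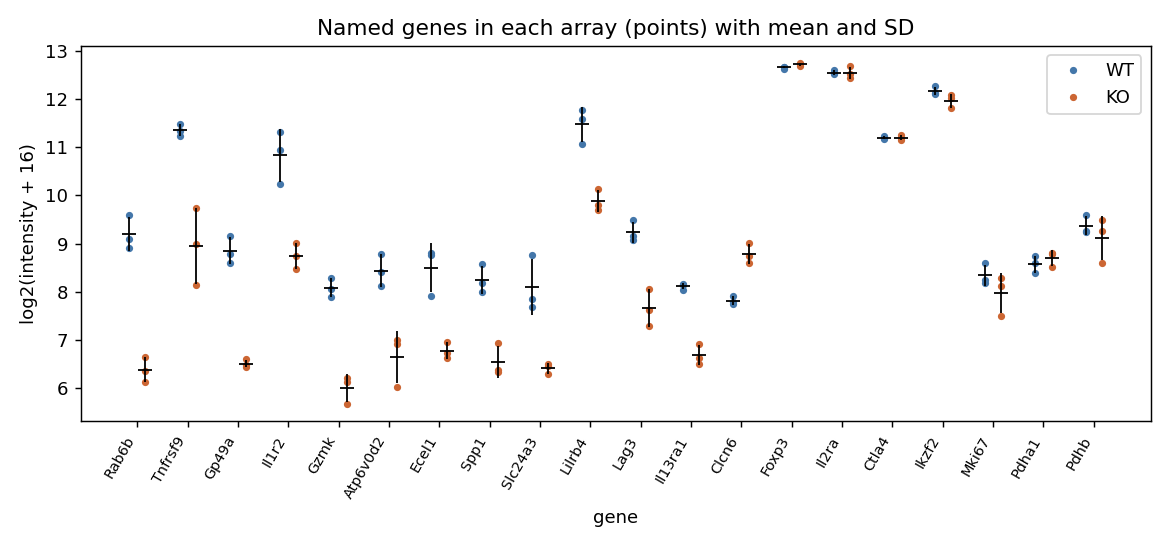
Log2(intensity + 16) of the genes past the threshold that the naming rule selects, and of the 7 genes named whatever their value, with 1 point per array and bars for mean and SD (n = 3 each). Rab6b lay at 9.20 in WT and 6.38 in KO, while Foxp3 lay at 12.66 and 12.73.

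At an unadjusted p of 0.05, 1482 genes differed (1066 lower, 416 higher), where chance alone would give about 695. Of these, 414 also differed by at least 1.5-fold, 350 lower and 64 higher. The count of 38 was 4 without WT replicate 1, 4 without WT replicate 2, 7 without WT replicate 3 and 11 without KO replicate 3. Without KO replicate 1, the array that lay apart, it was 37, of which 33 were among the 38. Of the 37 genes that passed besides Park7, Rab6b, Gp49a and Gzmk passed whichever array was left out, and the other 34 did not pass without at least 1 array (3 of the 37 passed without WT replicate 1, 3 without WT replicate 2, 6 without WT replicate 3, 32 without KO replicate 1, 26 without KO replicate 2 and 8 without KO replicate 3). Slc24a3, Vcam1 and, named after their values were seen, Gpr25 and Tnip3 passed in 0 of these 6 fits. Ahr and Fbxo44 passed in 1 of the 6, Nfil3 and Miip in 2 and Gm13157 in 3. An ordinary unmoderated test passed 0 genes after adjustment (1335 at an unadjusted p of 0.05), array weights gave 125, the mean of probe sets gave 60, and an adjusted p of 0.10 gave 74. With quantile normalization 87.3% of 55 passing genes were lower in KO, against 97.4% here. The count with a fold of 1.5 was 740 without KO replicate 2, 194 with a pseudocount of 64 and 208 with the mean of probe sets.

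The third comparison took gene lists fixed in advance, and the effector Treg list lay lowest by its test. Of its 33 tested members 30 had negative differences, with a median of -0.41 (camera adjusted p = 1.03e-09 with a preset correlation; adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone 7 members fell, and 1 (Lag3) over all genes. The 7 were Lag3 and, with differences given, the chemokine receptors Cxcr3 (-0.90) and Ccr8 (-0.69), the transcription factor Batf (-0.74), the costimulator Icos (-0.67), the inhibitory receptor Tigit (-0.92, and -0.61 without KO replicate 1) and the cytokine Il10 (-0.76). The wider Treg signature had a median of -0.17 over 28 members (-0.26 without KO replicate 2), 23 of them negative (adjusted p = 0.000106; adjusted p = 0.222 with an estimated correlation), and its adjusted p was 0.00605 without the genes within 10 Mb of Park7, a test chosen after the data were seen. Adjusted over the list alone 7 fell, Tnfrsf9, Tnfrsf1b, the integrin chain Itgae (-1.21), Gpr15 (-0.72), the ectoenzyme Nt5e (-0.49), Penk (-0.61) and Cd83 (-0.71), and 2 over all genes.

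Proliferation and interferon genes were also lower. The cell cycle list had a median of -0.35, with 38 of 42 members negative (adjusted p = 1.70e-07; adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone 7 members fell, the kinases Cdk1 (-0.88) and Aurkb (-0.52), the topoisomerase Top2a (-0.94), the replication helicase subunits Mcm6 (-0.90) and Mcm7 (-0.51), Cdc6 (-0.64) and Nusap1 (-0.58), and 0 over all genes; Mki67 differed by -0.37 (adjusted p = 0.590), by -0.14 without KO replicate 1 and by -0.24 without WT replicate 2. In the interferon list 36 of 38 members were negative, with a median of -0.37 (adjusted p = 2.16e-09; adjusted p = 0.222 with an estimated correlation). Psmb9 (-0.75), a subunit of the immunoproteasome, and the guanylate-binding Gbp6 (-0.78) fell when adjusted over the list alone, and 0 over all genes. The cytokine and chemokine receptor list passed with a median of -0.07 over 23 members (adjusted p = 0.0158; adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone 6 fell, Cxcr3, Ccr8, Il10, Ccl3 (-1.03), Ccl5 (-0.98) and Il21 (-0.79), and 0 over all genes. Without KO replicate 3 this list's adjusted p was 0.0581, and its median was -0.13 without WT replicate 1, -0.16 without KO replicate 1, -0.17 without WT replicate 3 and -0.18 without KO replicate 2.

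The naive or central T cell list was higher in KO, with 7 of 22 members negative and a median of 0.12 (adjusted p = 0.000870; adjusted p = 0.377 with an estimated correlation). No member passed over the list alone or over all genes; the 3 with the smallest p were Txk (0.59), Actn1 (0.45) and Il6ra (0.51). The immediate early list was also higher, with a median of 0.15 over 26 members (adjusted p = 0.0217; adjusted p = 0.377 with an estimated correlation), and no member passed over either; Fosb differed by 0.55, Hsp90aa1 by 0.38 and Fos by 0.39. Its adjusted p was 0.118 without WT replicate 3, 0.0554 without KO replicate 2 and 0.0555 without KO replicate 3, and its median was 0.060 without WT replicate 1 and 0.065 without KO replicate 3.

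Among metabolic lists, fatty acid oxidation was lower (median -0.23 over 20 members, adjusted p = 0.0150; adjusted p = 0.531 with an estimated correlation), and the isomerase Eci2 (-0.58) fell when adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were lower by a median of -0.15, with 59 of 73 negative (adjusted p = 0.0241; adjusted p = 0.560 with an estimated correlation); no member passed over the list alone or over all genes, and the 3 with the smallest p went both ways, Atp5j2 (1.00), Ndufc1 (-0.60) and Ndufv2 (-0.37). The adjusted p of fatty acid oxidation was 0.0663 without KO replicate 1 and 0.0538 without KO replicate 3; that of oxidative phosphorylation lay between 0.0506 and 0.0581 without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3. Without KO replicate 1 the median of fatty acid oxidation was -0.11 and that of oxidative phosphorylation -0.082. The pyruvate dehydrogenase complex and its regulators did not pass (median -0.22 over 13 members, -0.058 without KO replicate 1; adjusted p = 0.0944, 0.0472 without WT replicate 1). Adjusted over the list alone its kinase Pdk3 fell (-0.64), and no member over all genes. Lists that did not pass either were antioxidant genes (adjusted p = 0.0850, 0.0330 without WT replicate 1; Glrx -0.60, Srxn1 -0.76, Gpx4 -0.56), glutamine and one-carbon metabolism (0.191; Asns -0.52, Psat1 -0.54, Mthfd1 -0.37), glycolysis (0.390; Eno2 -0.49, Tpi1 -0.46, Pgk1 -0.43) and the tricarboxylic acid cycle (0.398; Mdh1 -0.45, Me2 0.35, Idh3g -0.29). The same held for mTOR and Akt signalling (0.212; Pik3cd 0.42, Ddit4 0.46, Foxo3 0.41), p53 and senescence (0.660; Gadd45g -0.47, Cdkn2c -1.19, Gadd45b -0.33), T cell receptor and NF-kB targets (0.703; Relb -0.38, Icam1 -0.47, Nfkb2 -0.38) and apoptosis (0.800; Birc2 -0.46, Bbc3 0.41, Bcl2l11 0.32). In none of these lists did a member pass when adjusted over the list alone. Without KO replicate 1 the differences were -0.67 for Cdkn2c, -0.24 for Pgk1, -0.25 for Mdh1 and -0.28 for Birc2; that of Foxo3 was 0.26 without WT replicate 1 and that of Bcl2l11 0.49 without WT replicate 3.

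Of the 8 marker lists of other cells, 4 passed camera with a preset correlation and 0 with an estimated one (0 at an unadjusted p of 0.05), and 0 passed fry in one direction (3 at an unadjusted p of 0.05). By fry's mixed p, for change in either direction, 4 passed, the B cell (adjusted p = 0.00202), NK (0.00420), conventional CD4 (0.00420) and macrophage (0.0272) lists. The B cell list was lower (median -0.60 over 9 members, adjusted p = 0.00544; adjusted p = 0.377 with an estimated correlation). The MHC class II genes H2-Ab1 (-1.24) and H2-Aa (-1.26) fell over all genes; adjusted over the list alone Cd74 (-0.67) and H2-Eb1 (-0.60) fell as well, and Faim3, now named Fcmr, rose (0.79). Cd79a (-0.23), Cd79b (-0.17) and Cd22 (-0.03), named after their values were seen, did not pass. A further member, not an MHC class II gene, differed by -0.74, the first quartile of the list, and did not pass either. In KO replicate 1 the median of this list lay -0.58 log2 units from the mean of the other 5 arrays. Those of the plasma cell, NK and erythroid lists lay at -0.47, -0.43 and -0.41. None of these values was corrected for that array's lower level over all tested genes. The macrophage and monocyte list was lower (median -0.25 over 9 members, adjusted p = 0.0217; adjusted p = 0.377 with an estimated correlation), with Vcam1 (-1.15) past the threshold over all genes and C1qc (-0.47) and Csf1r (-0.54) when adjusted over the list alone; its median was -0.40 without KO replicate 1, its adjusted p was 0.222 without KO replicate 2 and 0.0603 without KO replicate 3, and it turned higher with bright probe sets (0.741). The KO means of C1qc (5.91) and Csf1r (5.84) lay at or under the filter floor of 5.90, so the size of their differences is uncertain. The NK and cytotoxic list was lower (median -0.37 over 12, adjusted p = 0.0150, or 0.391 with an estimated correlation). Gzmk fell over all genes, and Ncr1 (-0.85) and Ccl5 fell when adjusted over the list alone; the list's adjusted p was 0.0506 without WT replicate 1. Plasma cell markers were lower (median -0.34 over 8, adjusted p = 0.0157; adjusted p = 0.391 with an estimated correlation) with no member past over the list alone or over all genes (Prdm1 -0.92, Igj, now Jchain, -0.85, Irf4 -0.41); the list's adjusted p was 0.167 without WT replicate 1 and 0.0656 without KO replicate 3. Conventional CD4 markers did not pass (adjusted p = 0.636), though Sostdc1 (-1.19) and Il21 fell when adjusted over that list alone. Neutrophil (0.703; Mmp9 0.12, Cxcr2 -0.16, Csf3r -0.04), dendritic cell (0.769; Bst2 -0.35, Zbtb46 -0.28, Ccr9 0.28) and erythroid and platelet markers (0.703; Car2 -0.30, Epor -0.19, Tfrc -0.26) did not pass. Without KO replicate 1 Car2 differed by -0.069, Epor by -0.072, Tfrc by -0.0044, Cxcr2 by 0.082 and Zbtb46 by -0.18, and leaving out other arrays also moved these and Mmp9, Csf3r, Bst2 and Ccr9 by over 1.5 times. The neutrophil list had a median of -0.01 (-0.038 without WT replicate 3 and 0.040 without KO replicate 2), while camera placed it higher and fry lower. Of the tested markers, 2 of 8 for plasma cells (Prdm1 and Irf4), 1 of 9 for macrophages, 3 of 12 for NK cells, 5 of 12 for conventional CD4 cells (Cxcr5, Ifng, Il21, Il7r and Tcf7), 2 of 6 for dendritic cells (Bst2 and Ccr9), 0 of 4 for neutrophils, 0 of 5 for erythroid cells and platelets and 0 of 9 for B cells also stood in another fixed list.

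In total 13 of 27 tested lists passed camera with a preset correlation, 11 lower and 2 higher. With an estimated correlation 0 passed in camera, where the Treg signature and the interferon list had unadjusted p-values of 0.00824 and 0.0164, and by fry, which tests whether a set's genes move on balance one way, 1 did (the Treg signature, adjusted p = 0.00613). The 2 members of the Treg signature past the threshold over all genes, Tnfrsf9 and Tnfrsf1b, lay within 10 Mb of Park7. No fry result without the genes in that window is given here, so their part in it stays open. By fry's mixed p, which tests change in either direction and does not compare a list with other genes, 16 of the 27 passed. Without KO replicate 3 the count was 7.

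**Figure D3:**
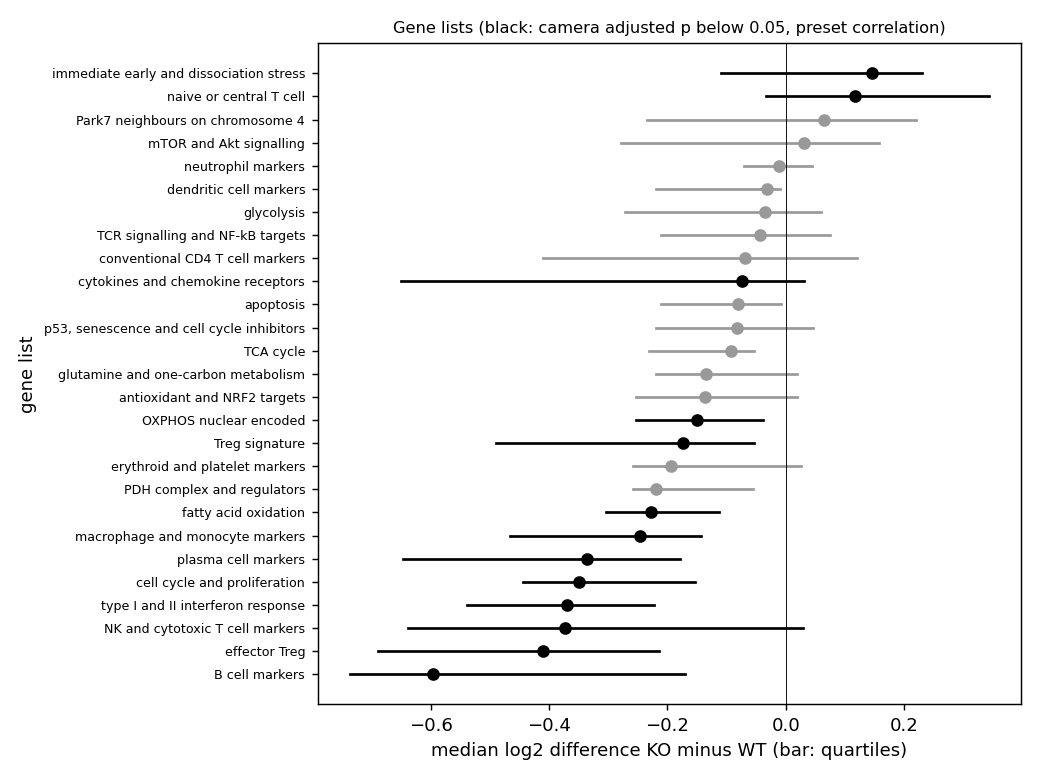
Median log2 difference, KO minus WT, of each of the 27 tested gene lists, with bars from the first to the third quartile of its members. Black marks the 13 lists past camera's adjusted p with a preset correlation; the B cell list has the lowest median, -0.60, and the effector Treg list lies at -0.41.

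The fourth comparison asked whether genes close to Park7 on chromosome 4 differed more often than others, since a knockout allele can carry neighbouring DNA of another mouse strain. Within 10 Mb of Park7, by gene positions of the GRCm38.p6 assembly, 35 of 165 tested genes (21.2%) differed at an unadjusted p of 0.05, against 1443 of 13706 other genes (10.5%; two-sided Fisher's exact test, odds ratio 2.29, 95% interval 1.52 to 3.36, p = 6.15e-05). Fisher's test takes genes as independent, although they share the same arrays, so its p and interval do not measure variation between mice. Of the 35 genes 21 were lower and 14 higher. Among the genes past the adjusted threshold 6 lay in this window, with Tnfrsf9, a direct neighbour of Park7, Tnfrsf1b, Miip (-1.13), Fbxo44 (6.60 ± 0.01 in WT and 5.60 ± 0.12 in KO, which is under the filter floor of 5.90) and Gm13157, now Zfp984 (-1.82), lower and Clcn6 higher. Miip, Fbxo44 and Gm13157 were named after their values were seen. The fixed list of Park7 neighbours did not pass camera (adjusted p = 0.191; 0.0181 with the mean of probe sets); its test and median (0.06, and 0.016 without WT replicate 1) were higher in KO and its mean (-0.05) lower. By fry's mixed p it passed (adjusted p = 0.00202), and in one direction it did not (0.482). Adjusted over the list alone Tnfrsf9 fell and Kif1b rose, and over all genes Tnfrsf9 fell.

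**Figure D4:**
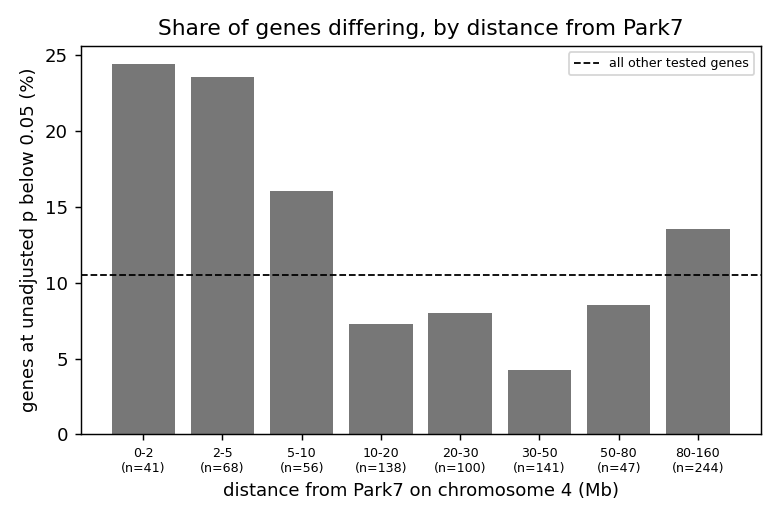
Percent of tested genes at an unadjusted p of 0.05 by distance from Park7 on chromosome 4, with the number of genes per bar and a dashed line at the share of all other genes, 10.5%. The share was 24.4% within 2 Mb, 23.5% from 2 to 5 Mb, 16.1% from 5 to 10 Mb and 7.25% from 10 to 20 Mb; it was 13.5% from 80 to 160 Mb.

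The fifth comparison asked whether probe sets of one gene differed by genotype more than the gene's other probe sets. The planned test, limma's diffSplice, passed 281 of 11451 genes, led by Vps13d, Ube4b, Lcn10, Clstn1 and Eif3d. That count cannot be read as 281 changed genes: on simulated arrays 68.2% of the test's calls were genes with no shifted probe set, or 55.9% with moderated noise. A test chosen after this was seen, which gives each probe set its own variance, had 1.25% and 5.93% of such calls in the same simulations and recovered 39.5% and 63.5% of the shifted genes. It passed 2 genes, Lcn10 (adjusted p = 0.0302) and Park7 (adjusted p = 0.0302). With it Clstn1 (0.218), Vps13d (0.256), Ube4b (0.657) and Eif3d (0.657) did not pass. In Lcn10, a lipocalin gene, 1 probe set lay at 8.76 ± 0.49 in WT and 4.84 ± 0.46 in KO (n = 3 each), while the gene's own value differed by -0.03. That gene value was dim, 6.46 in WT and 6.42 in KO against the filter floor of 5.90. What the 1 probe set measures was not tested, so its difference is not read as a change in exon usage. The diffSplice count was 446 without KO replicate 1 and 181 without WT replicate 3.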

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

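Chosen only after the results were seen were the tests of flanking DNA, of macrophage and B cell markers, of a mislabelled sample, of scaling as the whole of the difference in the lower genes, of the share of lower genes without KO replicate 1, of the spread within genes after quantile normalization, and of exon usage with a variance per probe set; the other tests were written down after a first look at leading genes and array correlations but before their own values were computed.

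No gene comparison uses the 30892 probe sets without a gene name. Among them, probe set 17421343 was higher in KO by 6.37 log2 units (SE 0.15) on the log2(intensity + 16) scale (limma adjusted p = 0.00271). The offset understates the difference, because the WT intensities lay under the added 16. Intensities were 7.19 ± 1.90 in WT and 1905 ± 179 in KO (SD, n = 3 each). Probe set 17421343 was the 1 probe set past the threshold that was higher in KO. Whether it matches a mouse gene, the targeting construct or flanking DNA of another strain was not tested, so the value is not read as the expression of a gene.

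Genes near Park7 differed more often than genes elsewhere. Against chromosome 4 genes over 30 Mb away the odds ratio was 2.44 (95% interval 1.45 to 4.09), so the excess was local to the window, and DNA of another strain carried with the knockout allele may account for part of it. Exon usage calls were also more frequent in the window (odds ratio 8.95 by diffSplice, and 5.42 at an unadjusted p with a variance per probe set, but 0 of 140 genes at its adjusted p), which is consistent with sequence variants under single probe sets. Without KO replicate 1 the odds ratio was 2.31 (1.55 to 3.37), which argues against that array as the source. The intervals of these odds ratios take genes as independent and do not measure variation between mice. No strain genotype was analysed here, so an effect of DJ-1 loss on neighbouring genes such as Tnfrsf9 stays open.

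Nearly all genes past the threshold were lower in KO. Centring arrays on their medians left 88.5% of the passing genes lower, between the bounds set in advance, so that test did not settle what scaling adds to the share. Scaling as the whole of the 37 lower genes' difference (median -1.32, upper quartile -1.13) would shift all genes alike. The median of all 13891 was -0.052 (lower quartile -0.20), which argues against scaling as the whole of that size. The 37 genes were selected for large differences, so these values do not bear on the share that was lower. In a fit without KO replicate 1, 91.9% of 37 passing genes were lower (95% exact interval 78.1% to 98.3%), which argues against that array as the source of the excess. The interval takes genes as independent, although they share the same arrays, and does not measure variation between mice. The median of -1.20 in KO replicates 2 and 3 decides nothing, as the genes were selected with those arrays. The sort for CD4 and high CD25 should remove B cells and macrophages. B cell markers nevertheless met the bound for fewer B cells in the KO sort (median -0.60). The members that fell when adjusted over the list alone were Cd74 and the MHC class II genes H2-Ab1, H2-Aa and H2-Eb1. Which cells these transcripts came from was not tested, so the met bound does not single out B cells. Cd74 was the brightest named (11.62 in WT, 10.95 in KO). A member outside the MHC class II genes differed by -0.74, the first quartile of the list. Cd79b (9.57 and 9.40), Cd79a (-0.23) and Cd22 (-0.03) differed less and Faim3 was higher (0.79). Macrophage markers (-0.25, with C1qc at 6.38 and 5.91) did not decide. The effector Treg list was lower (median -0.41, camera adjusted p = 0.377 with an estimated correlation). Each array averages all sorted cells, so these values do not tell whether expression per cell was lower. Lower values of effector genes and fewer other cells may both contribute, and their shares were not tested.

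KO replicate 1 lay apart from the other 5 arrays. Its Park7 value differed from the WT mean by -3.43 log2 units, which argues against a WT array under a KO label. The highest median deviation of any marker list was 0.02 (0.0157), within the bound set against added RNA of the listed cell types. These deviations were not corrected for that array's lower level. Its median over tested genes was 7.62 log2 units, against at least 7.79 in the others. That level understates any added RNA, so the test does not decide on it. Less RNA of such cells was not excluded either, as B cell, plasma cell, NK and erythroid markers lay at -0.58, -0.47, -0.43 and -0.41. Part of these 4 values may be that lower level. The spread of probe sets within genes was 1.55 times that of the other arrays, where no other array exceeded 1.04. This met the bound set for uneven signal along transcripts, from RNA quality or labelling. The measure uses no position along transcripts, so it cannot tell such unevenness from other noise in that array. In KO replicate 1, 407 genes lay over 1 log2 unit below the other arrays against 4 above. After quantile normalization the spread ratio was 1.58 (at most 1.03 in another array), which argues against scaling as the whole of that spread, whereas the mean correlation, 0.951 before and after, hardly responds to scaling and decides nothing, so scaling stays open for the rest of the pattern.

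The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave a result as large: 38 genes against at most 0 in the others, 281 exon usage genes against 127, 13 lists against 4, and an odds ratio near Park7 of 2.29 against 1.28.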

How the results depend on the processing

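Alternatives without the genes near Park7 and the exon usage test with a variance per probe set were chosen after the data were seen. Park7 stayed lower and past the threshold in every moderated limma fit run (-3.97 to -2.72) but not in the unmoderated test (adjusted p = 0.0905), and the odds ratio near Park7 stayed above 1 (1.48 to 16.6). The cause of the changes below was not tested, except that leaving out an array leaves fewer samples. The 38 genes became 60 with the mean of probe sets, 125 with array weights, 0 with an unmoderated test, 74 at an adjusted p of 0.10, and 3 probe sets in 1 gene when probe sets were tested one by one; leaving out an array gave 4 to 37. Genes with a fold of 1.5 numbered 194 with a pseudocount of 64 and 208 with the mean of probe sets, and 328 to 740 without an array. Lists numbered 0 with an estimated correlation and 1 by fry, and 7 to 13 without an array. Exon usage genes numbered 183 with bright probe sets, 2 with a variance per probe set, and 181 to 446 without an array. With the replicate number as a block 67 genes passed, 38 of them shared. The deviations of same-numbered arrays correlated at 0.15, 0.17 and 0.01. WT replicate 1 was closest to KO replicate 1 (-0.11 and -0.10 with KO replicates 2 and 3). WT replicate 2 was closest to KO replicate 2 (-0.19 and 0.092 with KO replicates 1 and 3). WT replicate 3 was closest to KO replicate 1 (0.03). So few values do not settle whether the numbers are pairs. No pairing was stated, so the main fit used no block.

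List p-values that crossed the threshold were: antioxidant genes 0.0454 without the filter, 0.0193 with bright probe sets and 0.0470 with trended variance; immediate early genes 0.0593 and Park7 neighbours 0.0181 with the mean of probe sets; cytokines 0.247 at the 60th percentile filter; and macrophage markers 0.0817 with a pseudocount of 64. Macrophage markers turned to higher by camera at the 60th percentile filter (0.824) and with bright probe sets (0.741). Without an array the ranges were 0.0472 to 0.490 for pyruvate dehydrogenase, 0.0309 to 0.0581 for oxidative phosphorylation, 0.0330 to 0.272 for antioxidant genes, 0.00492 to 0.0663 for fatty acid oxidation, 0.0132 to 0.118 for immediate early genes, 0.0116 to 0.0581 for cytokines, 0.00197 to 0.167 for plasma cells, 0.00245 to 0.222 for macrophages and 0.00535 to 0.0506 for NK cells.

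Genes near 0 that never passed changed sign: Cxcr2 (0.10 with array weights; -0.33 to 0.082 without an array), Csf3r (-0.11 to 0.00428 without an array), Epor (0.028 with bright probe sets), Il2ra (0.00399 with the mean of probe sets, 0.00325 with quantile normalization, 0.034 with median centring; -0.070 to 0.050), Ctla4 (0.00666, 0.030 and 0.016 with quantile normalization, median centring and array weights; -0.030 to 0.020), Vps13d (-0.21 to 0.011) and Lcn10 (0.00609 and 0.00247 with quantile normalization and median centring; -0.13 to 0.084). Of the other named gene values, 1865 kept direction and side, 75 passed newly and 66 no longer passed. Dim genes near the filter floor of 5.90 have little signal over background. Among them were Masp2 in WT (5.91) and C1qc (5.91), Csf1r (5.84), Cdc6 (5.90) and Ndufc1 (5.86) in KO.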
